A study of Mus musculus with 16 samples.

How the data were processed

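Total RNA of 16 left lungs was extracted with Trizol, turned into biotinylated cRNA and hybridized to Affymetrix Mouse Genome 430 2.0 arrays, 4 lungs per group, per the labels. The authors deposited 1 value per probe set and array on a log2 scale, already normalized between arrays. The method of summarisation and normalization is not given in the sources used here, and the submitters' processing notes name limma without a version or a role. The base of the logarithm was settled from the values, which ran from 2.58 to 15.2, the range that a scanner of 16 bits gives on a log2 scale. The values were used as deposited, with no further transformation. Raw intensities were not analysed here.

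Of 45101 features, 64 control probe sets were left out of the tests and kept for checks, which left 45037. Exactly 1 gene symbol was given for 34945 of them, several for 932 and none for 9160, and 34741 were matched by Entrez identifier to RefSeq genes of the mouse assembly GRCm38.p6, which gave the positions printed. Probe sets without a symbol were counted among the calls but not named. For gene lists and for the correlation between the sexes, each of 18193 genes was represented by its probe set with the highest mean over all arrays.

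Group means of the 4 groups were fitted for each probe set with limma 3.58.1 in R 4.3.3 (with the package data.table, version 1.17.8), with 12 residual degrees of freedom and 5.56 prior degrees of freedom. Differences were tested two-sided with limma's moderated test, and p was adjusted by Benjamini-Hochberg over all 45037 probe sets within each comparison, with calls at an adjusted p under 0.05. The comparisons were SHS minus air in females, in males and averaged over the sexes, the difference between the sexes in this effect (females minus males), and males minus females after air and after SHS. Errors given with log2 differences are standard errors of the model. In addition to the test, a call could be required to reach 1.5-fold.

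The 52 gene lists comprised 24 of gene function and 28 of cell type markers, including tissues that can be taken along with a lung, with 870 entries, of which 797 had a probe set and 73 had none. Lists with fewer than 4 measured genes were not tested, which left out the Y-linked list with 3 measured genes and left 51. They were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated for each list and with fry. Members were also counted with p adjusted over the list alone. Neither fry nor the counts of members compare a list with other genes.

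Genes were named by a rule: in each comparison the 10 called genes with the largest log2 difference in each direction, among probe sets with 1 symbol whose higher group mean lay above the median of all probe-set means, 7.02; where fewer than 5 were called, also the 5 in each direction with the smallest p; up to 4 members with the largest difference from each list with a call; and a set of single genes of type 2 inflammation, mucus, smoke metabolism and sex. Comparisons, tests, lists, naming rule and most alternatives were fixed before the data were examined. Genes outside the rule are said to have been chosen after their values were seen.

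Alternatives were quantile normalization, centring of each array on its median, leaving out probe sets below the 40th percentile of mean value, the replicate number as a block, the arrays of the groups compared alone, array weights, a trended robust prior, an adjusted p under 0.10, a 1.5-fold minimum, each array left out in turn, another way to represent a gene in the lists and the other list tests. Leaving out both SHS arrays numbered 4 was added after seeing the data. Groupings of the same arrays other than the real one were fitted in the same way, all 35 splits of 8 arrays into 4 and 4 for a comparison of 2 groups and 100 drawn with a fixed seed for the others. Control probe sets were compared between groups with two-sided exact permutation tests, and shares of genes were given exact Clopper-Pearson 95% intervals. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

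The steps were tested on simulated data of 45037 probe sets with 50 changed at each fold. At 1.25-fold, 38% of the changed probe sets were called in the right direction in females, 20% in males, 72% in the averaged effect and 14% in the interaction. At 1.5-fold these shares were 78%, 76%, 98% and 38%, at 2-fold 100%, 100%, 100% and 96%, and at 3-fold 98% in each. Unchanged probe sets called numbered 12, 11, 9 and 6. A cell cycle list shifted in simulated SHS females was called there, in the averaged effect and in the interaction, and not in males. The simulated noise was drawn independently for each probe set, so genes were not correlated as they can be in real lungs. The simulation therefore cannot show how often the tests, camera above all, make wrong calls on the real arrays.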

Results

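Left lungs of 16 Balb/c mice, an inbred strain commonly used as a model of allergic asthma, were profiled at 23 weeks of age on Affymetrix Mouse Genome 430 2.0 arrays, with 1 lung on each array. The mice formed 4 groups of 4. Females and males had spent gestation in mothers breathing either filtered air or second-hand smoke (SHS). The SHS was sidestream smoke carrying 10 mg/m3 of particles for 5 h per day on 7 days per week. All 16 mice were sensitized with ovalbumin (OVA), an egg protein used as a model allergen, by injection at 19 and 21 weeks and breathed OVA aerosol in weeks 22 and 23. Every comparison of SHS with air was thus made in lungs challenged with an allergen, and no lung without OVA was in the series. The values were log2 intensities of 45037 probe sets. The 4 mice per group limited the precision.

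Arrays of the same sex correlated across probe sets at 0.990 to 0.998 and arrays of different sexes at 0.959 to 0.974. The first principal component, which carried 72.8% of the variance, separated the sexes. The SHS female replicate 4 had a mean correlation of 0.992 with its own group and 0.995 with the air females. Litters and mothers were not given in the sources used here, so siblings could not be told from unrelated mice.

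The comparison within females asked how the allergen-challenged lung of an adult female differed between smoke and air in utero. Cxcl3, a chemokine that attracts neutrophils (chromosome 5, 90786101 to 90788093), was 10.7-fold higher after SHS, a log2 difference of 3.42 ± 0.32 (SE, n = 4 and 4, adjusted p = 7.25e-05 in limma). Its chromosomal neighbours Cxcl5 and Cxcl2, which act on the same cells, rose by 2.42 ± 0.36 (adjusted p = 0.00118) and 1.67 ± 0.28 (adjusted p = 0.0027). Arg1, the arginase of alternatively activated macrophages, rose 6.27-fold (adjusted p = 0.00808), and Ccl24, a chemokine for eosinophils, 4.97-fold (adjusted p = 0.0199). Timp1, an inhibitor of matrix metalloproteinases, rose by 2.13 ± 0.23 (adjusted p = 0.000187), Ch25h, which makes 25-hydroxycholesterol, by 1.75 ± 0.17 (adjusted p = 7.25e-05) and the acute-phase protein Saa3 by 1.89 ± 0.33 (adjusted p = 0.00391). The other genes among the 10 named for the largest rise were Ocstamp, a gene of multinucleated cell formation (2.36 ± 0.42, adjusted p = 0.00431), and Fxyd4, a regulator of the sodium pump (1.56 ± 0.27, adjusted p = 0.00391).

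Decreases in SHS females were smaller. Esm1, an endothelial proteoglycan, fell by 1.34 ± 0.31 (adjusted p = 0.0249), Pon1, a lipoprotein-bound esterase, by 1.01 ± 0.24 (adjusted p = 0.0284), and the matrix protein gene Abi3bp by 0.87 ± 0.19 (adjusted p = 0.0189). Scgb3a2, a secretoglobin of airway club cells, fell by 0.84 ± 0.16 (adjusted p = 0.00692) and Dbp, a transcription factor driven by the circadian clock, by 0.75 ± 0.14 (adjusted p = 0.0074). Chrdl1 (adjusted p = 0.0485), Grp (adjusted p = 0.04), Atp6v1b1 (adjusted p = 0.00175), Alad (adjusted p = 0.0475) and Mamdc2 (adjusted p = 0.00583) had log2 differences of -0.76, -0.76, -0.74, -0.73 and -0.69. For each of the 10 rising and 10 falling genes, all 4 SHS arrays lay beyond the air mean, and for 9 of the rising and 8 of the falling genes all 4 lay beyond every air array. With 1 of the 16 arrays left out in turn, 13 of these 20 genes were called each time. Ccl24 was called in 11 of the 16 fits, Esm1 and Pon1 in 10, Abi3bp in 12, Grp in 6, Alad in 4 and Chrdl1 in 2. The highest adjusted p was 0.0766 for Ccl24 and 0.133 for Grp without SHS female replicate 2 and 0.102 for Pon1 without SHS female replicate 3. It was 0.0779 for Esm1, 0.0631 for Abi3bp and 0.143 for Chrdl1 without air female replicate 3, and 0.154 for Alad without air female replicate 4.

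Among gene lists, genes of cell division moved furthest in females. In the cell cycle list, 24 of 25 measured members rose (24 when adjusted over the list alone), with a median log2 difference of 0.93 (camera adjusted p = 1.68e-33, and adjusted p = 0.113 with an estimated correlation). The ribonucleotide reductase subunit Rrm2 rose by 1.43 ± 0.16 and the mitotic regulator Birc5 by 1.38 ± 0.15, and the proliferation marker Mki67 and the topoisomerase Top2a by 1.30 and 1.23. Of 27 genes of acute inflammation, NF-kB and IL-17 responses, 11 rose (17 adjusted over the list alone) and none fell, with a median of 0.39 (camera adjusted p = 2.99e-10, and adjusted p = 0.113 with an estimated correlation). Of 27 IL-13 target genes, which respond to the type 2 cytokine interleukin 13 and include Arg1, Ccl24, Timp1 and Saa3, 10 rose (14 adjusted over the list alone), with a median of 0.34 (camera adjusted p = 5.65e-09, and adjusted p = 0.313 with an estimated correlation). Saa3 is also on the acute inflammation list, so these 2 calls are not independent. Other IL-13 targets were not called in females, among them the mucins Muc5ac (0.34, adjusted p = 0.285) and Muc5b (-0.31, adjusted p = 0.347). Chil3 (0.18, adjusted p = 0.113) and Clca1 (-0.03, adjusted p = 0.924) were not called either, but lay near the top of the range of the arrays, where a change can be hidden. The cytokine genes Il4, Il5 and Il13 themselves had log2 differences of 0.36, 0.47 and 0.47 and did not pass the test in females (adjusted p = 0.28, 0.0866 and 0.217). The list of type 2 cytokines, receptors and regulators was not called (adjusted p = 0.13), with 3 of 22 members higher, among them Irf4, Il13ra2 and Il33 at 0.81, 0.81 and 0.52.

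Lists of metabolism and stress responses moved by smaller amounts in SHS females, some higher and 1 lower. Of 26 oxidative phosphorylation genes 4 rose (14 adjusted over the list alone), with a median of 0.17 and the ATP synthase gene Atp5g1 at 0.48 (camera adjusted p = 6.23e-10, and adjusted p = 0.23 with an estimated correlation). Of 22 genes of the heat shock and unfolded protein response 7 rose (10 adjusted over the list alone), with a median of 0.19 (camera adjusted p = 2.21e-06, and adjusted p = 0.313 with an estimated correlation). Its leading members Sdf2l1, Manf, Pdia4 and Creld2, at 0.81, 0.72, 0.69 and 0.68, act in the endoplasmic reticulum. Of 18 hypoxia and glycolysis genes 4 rose (9 adjusted over the list alone, with 1 lower), among them Pgk1 at 0.47 (camera adjusted p = 0.00692, and adjusted p = 0.21 with an estimated correlation). Of 21 apoptosis and p53 target genes 4 rose (5 adjusted over the list alone), led by Gadd45g at 0.51 (camera adjusted p = 0.0089, and adjusted p = 0.319 with an estimated correlation). In the list of aryl hydrocarbon receptor and xenobiotic metabolism genes 3 of 18 fell (7 lower and 2 higher adjusted over the list alone), namely Fmo2 (-0.58), Ephx1 (-0.47) and Ces1d (-0.43), all enzymes of drug metabolism (camera adjusted p = 0.00712, and adjusted p = 0.341 with an estimated correlation). Cyp1a1, the classical receptor target, had a difference of 0.20 (adjusted p = 0.689).

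Of the airway epithelial lists, those of club and ciliated cells were lower in SHS females by camera, and that of goblet cells was not called (adjusted p = 0.944). The 10 club cell markers had a median of -0.41 (camera adjusted p = 7.14e-05, and adjusted p = 0.313 with an estimated correlation), with Scgb3a2 called over all probe sets and 6 lower when adjusted over the list alone. The 15 ciliated cell markers had a median of -0.19 with no single member called by either adjustment (camera adjusted p = 0.000266, and adjusted p = 0.433 with an estimated correlation). The abundant club cell protein gene Scgb1a1 (-0.02, adjusted p = 0.919) and the surfactant gene Sftpc (0.03, adjusted p = 0.886) were not called, but both lay near the highest values of the arrays, where a change can be hidden by saturation. Of 18 circadian clock genes 5 fell and 1 rose (10 and 4 adjusted over the list alone), with the repressor Nfil3 at 0.78 and Dbp at -0.75 (camera adjusted p = 0.00539, and adjusted p = 0.313 with an estimated correlation).

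Immune cell markers of females were higher in several lists. The medians of 11 T cell markers and 11 B cell markers were 0.23 and 0.35 (camera adjusted p = 0.00157 and 0.00483, and adjusted p = 0.313 and 0.473 with an estimated correlation). In each, 1 member was called (4 and 2 adjusted over the list alone), the CD8 chain Cd8b1 at 0.40 and the low-affinity IgE receptor Fcer2a at 1.03. Of 19 complement and coagulation genes 4 rose (8 higher and 1 lower adjusted over the list alone), among them complement factor Cfb at 0.63 (camera adjusted p = 0.00359, and adjusted p = 0.21 with an estimated correlation). Of 17 regulatory T cell and anti-inflammatory genes 2 rose (2 adjusted over the list alone), Il10 at 0.71 and Ctla4 at 0.56 (camera adjusted p = 0.0065, and adjusted p = 0.33 with an estimated correlation). Of 27 genes of the Th1 and interferon-gamma response 2 rose (2 adjusted over the list alone), with Socs1 at 0.61 (camera adjusted p = 0.00539, and adjusted p = 0.473 with an estimated correlation). Ifng itself was not called (0.33, adjusted p = 0.159). The 9 eosinophil markers, with a median of 0.15, were not called (adjusted p = 0.878), but they were called higher without SHS female replicate 4 (adjusted p = 0.0151).

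In all, 1294 of 45037 probe sets were called in females, 1061 higher and 233 lower, from 922 genes, and 366 of them changed at least 1.5-fold. With quantile normalization, which made 1220 calls, the share of higher probe sets was 70.6% in place of 82.0%. Of the 51 lists tested 24 were called by camera, 17 higher and 7 lower, and 16 of these were called whichever array was left out. The other 8 were neutrophils (median 0.25, camera adjusted p = 0.0172), alveolar macrophages (0.25, 0.0161), dendritic cells (0.21, 0.0265), extracellular matrix (0.20, 0.0297) and ribosomal proteins (0.08, 0.0143), which were higher, and lung development (-0.11, 0.0172), endothelium (-0.11, 0.0123) and fibroblasts (-0.25, 0.0471), which were lower. Their adjusted p with an estimated correlation was 0.313, 0.313, 0.341, 0.666, 0.473, 0.477, 0.558 and 0.505. Adjusted over the list alone, 2 neutrophil, 4 alveolar macrophage, 5 dendritic cell and 5 matrix genes were higher. The highest adjusted p was 0.0724, 0.209 and 0.0841 for alveolar macrophages, extracellular matrix and ribosomal proteins without air female replicate 3. It was 0.172 for neutrophils without air female replicate 1 and 0.0688 for dendritic cells without air female replicate 4. It was 0.127, 0.0985 and 0.317 for lung development, endothelium and fibroblasts without SHS female replicate 2. The SHS female replicate 4 had a cell cycle median of 0.48, nearer to air than the other 3 at 0.97 to 1.19. Its eosinophil median of -0.85 lay below both the other 3 (0.15 to 0.44) and all 4 air females (-0.06 to 0.01). Without both SHS arrays numbered 4, an alternative chosen after seeing the data, 3954 probe sets were called in females. The count was 3604 without SHS female replicate 4 alone. It was 657, 683 and 723 without SHS female replicates 1, 2 and 3, and 674, 688 and 797 without air female replicates 2, 3 and 4. A fit of the 8 female arrays alone called 448.

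The comparison within males asked the same of male lungs. Cxcl5 rose 8.64-fold after SHS, a log2 difference of 3.11 ± 0.36 (n = 4 and 4, adjusted p = 0.000175 in limma), and Cxcl3 5.66-fold (adjusted p = 0.000392). Aldh1a3, an enzyme that makes retinoic acid (chromosome 7, 66390892 to 66427477), rose by 2.43 ± 0.16 (adjusted p = 8.68e-07), Timp1 by 2.43 ± 0.23 (adjusted p = 4.19e-05) and Saa3 by 2.38 ± 0.33 (adjusted p = 0.000623). Cxcl13, a chemokine that draws B cells, rose 4.73-fold (adjusted p = 0.0068) and Ccl24 4.25-fold (adjusted p = 0.0261). Chl1, a neural cell adhesion gene, rose by 1.97 ± 0.26 (adjusted p = 0.000437), Fxyd4 by 1.90 ± 0.27 (adjusted p = 0.000733) and Ocstamp by 1.87 ± 0.42 (adjusted p = 0.0142).

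In the falling direction the male lungs were led by Bex1, a neuronal signalling adaptor on the X chromosome, which fell by 1.86 ± 0.28 (adjusted p = 0.00117). Gpnmb, a glycoprotein of lipid-laden macrophages, fell by 1.61 ± 0.36 (adjusted p = 0.0136), the integrin-related Itgbl1 by 1.32 ± 0.13 (adjusted p = 4.82e-05), Esm1 by 1.21 ± 0.31 (adjusted p = 0.0304) and Pon1 by 1.07 ± 0.24 (adjusted p = 0.0149). Myh7, a cardiac and slow muscle myosin, had a difference of -0.94 (adjusted p = 9.99e-05), Chrdl1 -0.93 (adjusted p = 0.000733), Aspn -0.89 (adjusted p = 0.00081), Fam107a -0.85 (adjusted p = 0.0396) and Adh7 -0.85 (adjusted p = 0.00586). All 4 SHS arrays lay beyond the air mean for each of these 20 genes, and beyond every air array for 10 of the rising and 9 of the falling genes. With 1 array left out in turn, 15 of the 20 were called each time. Ccl24 was called in 11 of 16 fits (highest adjusted p = 0.0816, without SHS male replicate 1), Ocstamp in 14 (0.0543, without SHS male replicate 3). Esm1 was called in 11, Pon1 in 13 and Fam107a in 9 (0.104, 0.058 and 0.118, each without air male replicate 3).

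The cell cycle, IL-13 target and acute inflammation lists were called in males too. In the cell cycle list 23 of 25 members rose (24 adjusted over the list alone), with a median of 0.84 and Birc5, Rrm2, Aurkb and Top2a at 1.43, 1.33, 1.11 and 1.05 (camera adjusted p = 9.75e-26, and adjusted p = 0.168 with an estimated correlation). Of 27 IL-13 target genes 17 rose (20 adjusted over the list alone), with a median of 0.60 and Arg1 at 1.82 ± 0.51 (camera adjusted p = 1.63e-14, and adjusted p = 0.186 with an estimated correlation). Il4, Il5 and Il13 were at 0.34, 0.37 and 0.56 and were not called (adjusted p = 0.254, 0.144 and 0.0965), nor was their list (adjusted p = 0.474). Of 27 acute inflammation genes 14 rose (16 adjusted over the list alone), with a median of 0.44 and Cxcl2 at 1.77 (camera adjusted p = 5.82e-12, and adjusted p = 0.116 with an estimated correlation). The goblet cell markers, genes of mucus-secreting airway cells, had a median of 0.49 (camera adjusted p = 0.00164, and adjusted p = 0.525 with an estimated correlation). Of 9 markers 3 were higher (4 adjusted over the list alone), including Agr2 at 0.96 and the mucin Muc5ac at 0.59. All of them except Gp2 were also on the list of IL-13 targets, so the calls of these lists are not independent. Muc5b (0.21, adjusted p = 0.488), Clca1 (0.17, adjusted p = 0.269) and the macrophage genes Chil3 (0.07, adjusted p = 0.567) and Retnla (0.15, adjusted p = 0.186) were not called. The last 3 lay near the top of the range of the arrays, where a change can be hidden, and Retnla was called in the effect averaged over the sexes (0.18, adjusted p = 0.0193). The chitinase-like Chil4 (0.60, adjusted p = 0.0229) and the eotaxin Ccl11 (0.82, adjusted p = 0.026) rose.

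The list of NRF2 targets was called in males and not in females (adjusted p = 0.0674), and its difference between the sexes was not called (adjusted p = 0.0656). Of 29 NRF2 targets and antioxidant genes 10 rose and 1 fell (12 and 5 adjusted over the list alone), led by the glutathione peroxidase Gpx2 at 0.88, heme oxygenase Hmox1 at 0.85 and the glutathione synthesis gene Gclc at 0.71 (camera adjusted p = 0.00228, and adjusted p = 0.186 with an estimated correlation). In the aryl hydrocarbon receptor and xenobiotic list 1 of 18 rose and 3 fell (1 and 5 adjusted over the list alone), with Cyp1b1 at 0.66, Ces1d at -0.56, Fmo2 at -0.49 and Ephx1 at -0.46 (camera adjusted p = 0.00481, lower, and adjusted p = 0.43 with an estimated correlation). Cyp1a1 was not called (0.12, adjusted p = 0.801). Heat shock and unfolded protein genes rose in 7 of 22 (11 adjusted over the list alone), with Sdf2l1 at 0.83 (camera adjusted p = 1.06e-07, and adjusted p = 0.261 with an estimated correlation). Oxidative phosphorylation genes rose in 7 of 26 (8 adjusted over the list alone), with Atp5g1 at 0.60 (camera adjusted p = 1.54e-05, and adjusted p = 0.43 with an estimated correlation). Hypoxia and glycolysis genes rose in 2 of 18 (7 higher and 2 lower adjusted over the list alone), with Ldha at 0.45 (camera adjusted p = 0.0126, and adjusted p = 0.186 with an estimated correlation).

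Among immune lists of males, complement and coagulation had 2 of 19 members higher (6 adjusted over the list alone), with Cfb at 0.73 (camera adjusted p = 0.00189, and adjusted p = 0.168 with an estimated correlation). Neutrophil markers had 2 of 11 higher (4 adjusted over the list alone; camera adjusted p = 0.00384, and adjusted p = 0.229 with an estimated correlation). These were the decoy interleukin 1 receptor Il1r2 at 1.08 and Cxcr2, the receptor of Cxcl2, Cxcl3 and Cxcl5, at 0.59. Dendritic cell markers had 3 of 11 higher (4 adjusted over the list alone), with Ccl17 at 1.09 (camera adjusted p = 0.0362, and adjusted p = 0.43 with an estimated correlation). The type I interferon list had 2 of 23 higher (10 adjusted over the list alone), with Ifi27l2a at 0.57 and Mx1 at 0.40 (camera adjusted p = 0.00273, and adjusted p = 0.632 with an estimated correlation). The eosinophil list was not called (adjusted p = 0.936, and 0.369 without SHS male replicate 4). The cardiac muscle list, which marks heart or pulmonary vein tissue taken with a lung, had a median of 0.80 in SHS males (camera adjusted p = 0.000537, and adjusted p = 0.597 with an estimated correlation). None of its 13 members was called (5 adjusted over the list alone). Its per-lung medians also spanned -0.84 to 0.55 among air females.

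In males 2332 probe sets were called, 1382 higher and 950 lower, from 1653 genes, and 463 changed at least 1.5-fold. With the 5′ minus 3′ difference of control probe sets, a sign of RNA integrity, as a covariate the count was 1178. This difference was -0.60 to -0.58 in SHS male replicates 1 to 3, above all 4 air males (-0.77 to -0.72), and -0.88 in SHS male replicate 4. Camera called 14 lists, 13 higher and 1 lower, and 12 of these were called whichever array was left out. The exceptions were the type I interferon list (adjusted p = 0.152 without SHS male replicate 3) and dendritic cells (0.117 and 0.0649 without air male replicates 3 and 4). The SHS male replicate 4 had a cell cycle median of 0.54 against 0.83 to 0.96 in the other 3 and an eosinophil median of -0.50 against 0.13 to 0.24. Without both arrays numbered 4 the count was 3315. The count was 1282 and 1178 without air male replicates 1 and 3, and 1220, 1370 and 1073 without SHS male replicates 1, 2 and 3.

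**Figure D1:**
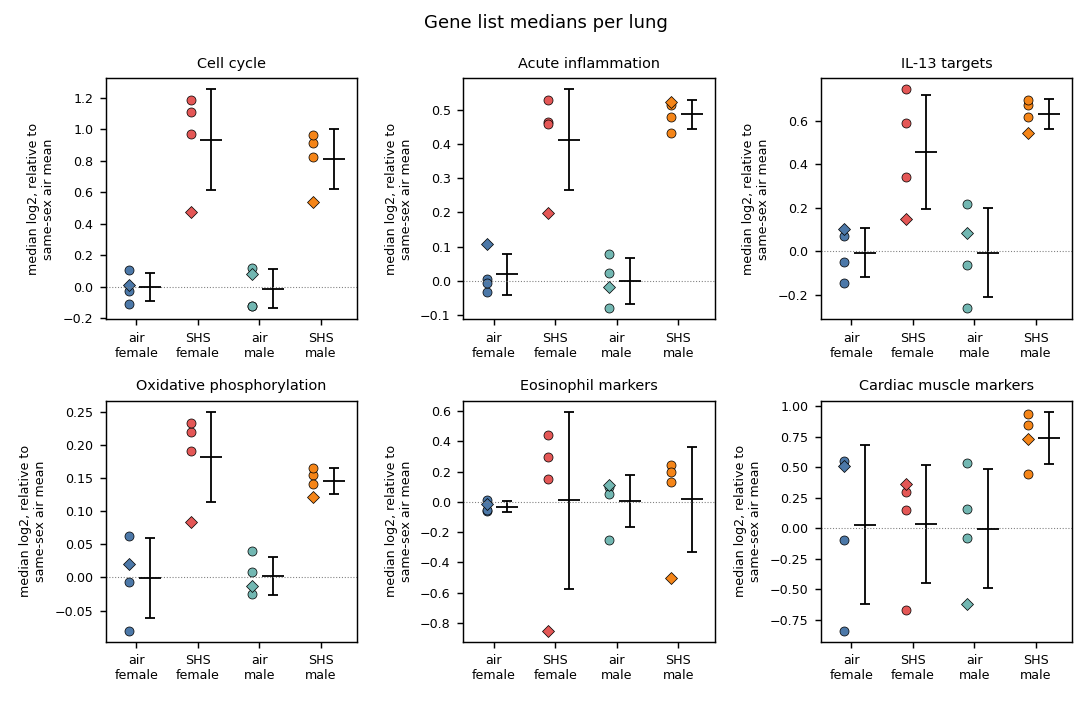
Median log2 value of 6 gene lists in each lung, relative to the mean of the air lungs of the same sex (vertical axes), for the 4 groups of 4 lungs (horizontal axes), with diamonds for replicate 4 and bars for the group mean and SD. In the cell cycle panel the 8 SHS lungs lie between 0.48 and 1.19, above all 8 air lungs, of which the highest is at 0.12.

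**Figure D2:**
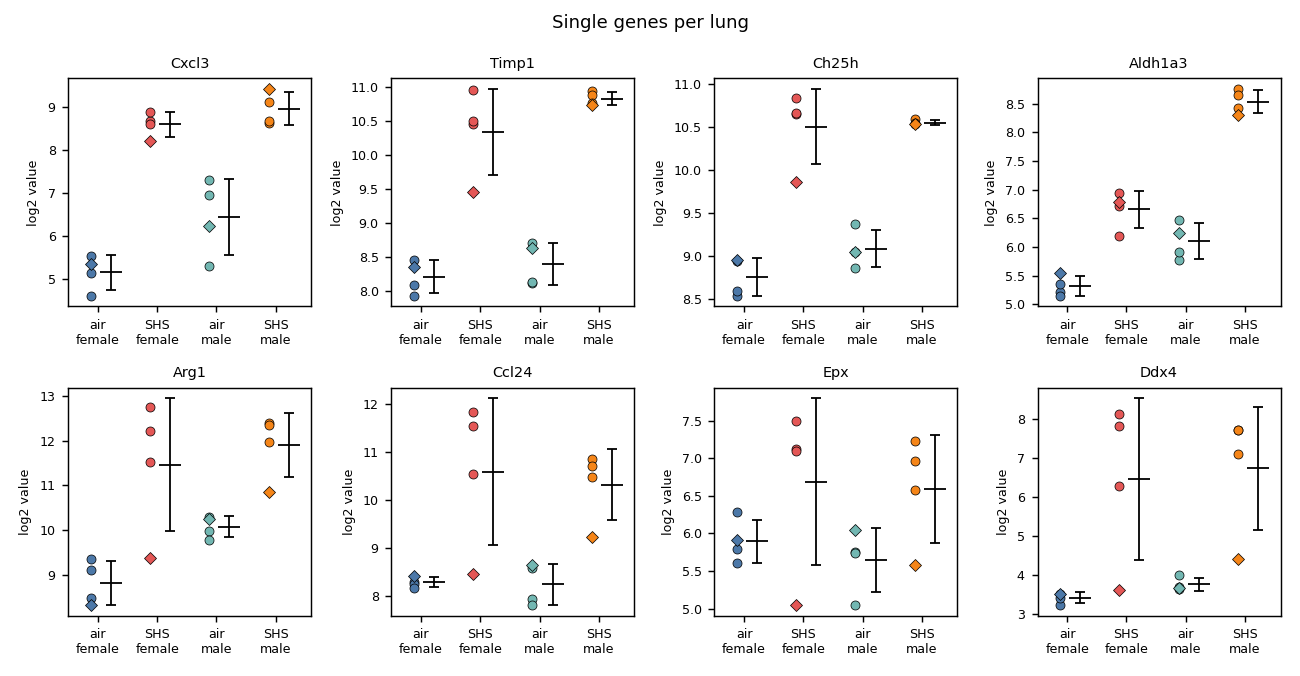
Log2 values of 8 genes in each lung (vertical axes) for the 4 groups of 4 lungs, with diamonds for replicate 4 and bars for the group mean and SD. Cxcl3 is higher in all 4 SHS females than in every air female, while Epx in the SHS female replicate 4 is at 5.05 and in the other 3 SHS females at 7.09 to 7.50 (Epx and Ddx4 were chosen after their values were seen).

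Averaging the SHS effect over the sexes used all 16 lungs and gave the mean change of the 2 sexes, which need not be shared by both. Cxcl3 rose by 2.96 ± 0.23 (adjusted p = 9.68e-07 in limma), Cxcl5 by 2.77 ± 0.25, Timp1 by 2.28 ± 0.16, Arg1 by 2.24 ± 0.36 and Ccl24 by 2.20 ± 0.37. These were followed by Saa3 (2.13), Ocstamp (2.12), Aldh1a3 (1.89, adjusted p = 9.56e-08), Cxcl13 (1.83) and Fxyd4 (1.73). Esm1 fell by 1.28 ± 0.22, Bex1 by 1.07 ± 0.20, Pon1 by 1.04 ± 0.17, and Gpnmb by 0.96 ± 0.25, and Itgbl1 fell as well (adjusted p = 3.79e-06). The averages of Bex1 and Gpnmb came mostly from males, since in females they were at -0.28 and -0.31 (adjusted p = 0.698 and 0.737). Myh7, Chrdl1, Scgb3a2, the carboxylesterase Ces2b and Abi3bp were at -0.78, -0.78, -0.75, -0.74 and -0.73. All 20 were called whichever array was left out. With the sexes averaged, the type 2 cytokines Il5 (0.42, adjusted p = 0.0113) and Il13 (0.52, adjusted p = 0.0192) were called and Il4 (0.35, adjusted p = 0.0619) was not. In total 4652 probe sets were called, 2997 higher and 1655 lower, with 406 changed at least 1.5-fold. The count was 6983 without SHS female replicate 4 and 7520 without both arrays numbered 4.

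Camera called 20 lists in the averaged effect, 16 higher and 4 lower. Among the higher ones, 24 of 25 cell cycle genes (24 adjusted over the list alone), 18 of 27 IL-13 targets (20) and 17 of 27 acute inflammation genes (19) rose (camera adjusted p = 3.66e-31, 1.04e-13 and 7.12e-13, and adjusted p = 0.0954, 0.183 and 0.0888 with an estimated correlation). The 4 lower lists were those of club cells, ciliated cells, the circadian clock, and xenobiotic metabolism (camera adjusted p = 0.00264, 0.00681, 0.00701 and 0.00264, and adjusted p = 0.442, 0.688, 0.281 and 0.297 with an estimated correlation). Left out in turn, 1 array ended the calls of extracellular matrix and ribosomal proteins (0.0898 for both without air female replicate 3), goblet cells (0.123 without SHS female replicate 1) and cardiac muscle (0.111 without air female replicate 1), and the other 16 lists were called each time. The club cell genes Scgb3a2, Gsta3, Cyp2f2 and Cckar were at -0.75, -0.41, -0.38 and -0.31. With an estimated correlation none of the 51 lists was called in any comparison, the smallest adjusted p was 0.0888, and in the averaged effect 9 lists had an unadjusted p under 0.05.

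The changes of the 2 sexes were alike in direction. Across 18193 genes, which are not independent replicates, the SHS effect in females correlated with that in males at r = 0.624 ± 0.108 (jackknife SE over arrays) and a Spearman rho of 0.437. Of the probe sets called in each sex, 677 were called in both in the same direction, 600 higher and 77 lower, where 32.6 and 4.92 would be shared at random, and 1 was called in opposite directions. Of the probe sets called in females 94.4% had the same sign in males, and of those called in males 90.3% had the same sign in females.

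**Figure D3:**
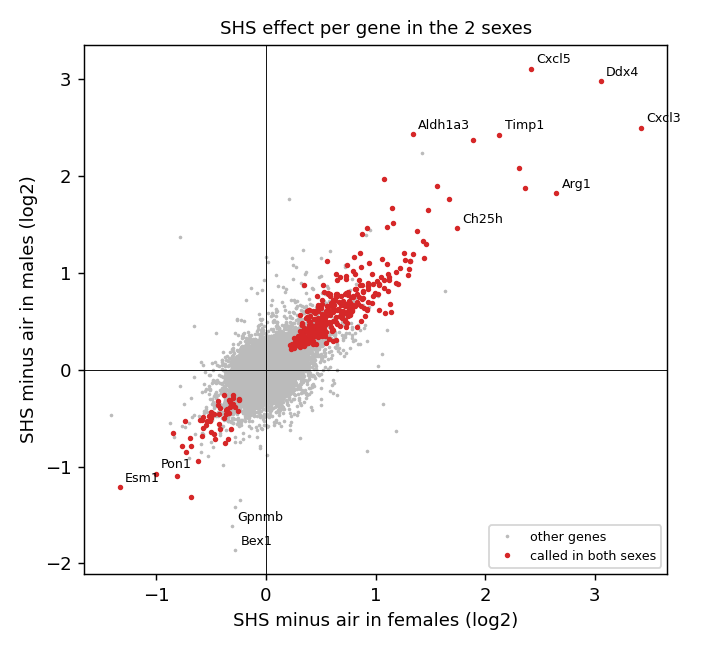
SHS minus air log2 difference of each of 18193 genes in females (horizontal axis) and in males (vertical axis), with genes called in both sexes in red. The 2 differences correlate at r = 0.624, and Cxcl3, at 3.42 in females and 2.50 in males, lies near the upper right end.

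Whether the SHS effect differed between the sexes was tested as the interaction of SHS with sex. The array controls described below differed by sex on every array. A difference of the SHS effect between the sexes could therefore not be separated from a difference in labelling. No probe set was called by limma, the smallest adjusted p was 0.141, and 3709 probe sets had an unadjusted p under 0.05. The smallest p on the side of a higher effect in females belonged to Znrd1as (0.54 ± 0.09) and Cfap298 (0.57 ± 0.10, both adjusted p = 0.141). They were followed by Ccng1, Itgb3bp and Fastkd2 (0.49, 0.66 and 0.42, adjusted p = 0.21). On the side of a higher effect in males stood Aldh1a3, at 1.34 in females and 2.43 in males, a difference of -1.09 ± 0.23 (adjusted p = 0.34). It was followed by Osmr, Egfl7, Gpx2 and Igfbp4 (-0.39, -0.62, -0.54 and -0.46, adjusted p = 0.383). None of these 10 genes passed the test. Camera called 14 lists, among them cardiac muscle (-0.64, adjusted p = 0.00197) and goblet cells (-0.39, adjusted p = 0.00235), both lower in females. With an estimated correlation the smallest adjusted p was 0.756 and fry called 0 lists. Only 2 of the 14, goblet cells and the apoptosis and p53 targets (0.12, adjusted p = 0.00488), were called whichever array was left out, and cardiac muscle had an adjusted p of 0.0522 without SHS female replicate 2.

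The sexes themselves were compared after air and after SHS. Xist, the RNA that silences the second X chromosome of females, was higher in air females than in air males, with a log2 difference of males minus females of -7.97 ± 0.15 at 1 probe set and -4.95 at the brightest. The Y-linked genes Eif2s3y, Kdm5d and Uty were 6.90, 5.69 and 5.31 higher in males (adjusted p = 6.28e-16, 1.32e-14 and 1.07e-16 in limma), and Uty was 2.95 higher at its brightest probe set. In the sex without the transcript the -7.97, 6.90, 5.69 and 5.31 were measured against values of 3.65, 3.80, 3.30 and 3.35. Control probe sets without their RNA had group means of 3.52 to 3.61, so these 4 differences are lower bounds. Broadly expressed genes outside the Y chromosome followed, with Sdc4, Bptf, Nr2c2, Actb, Prrc2c, Fubp1 and Malat1 higher in air males by 4.17, 4.01, 3.94, 3.74, 3.71, 3.63 and 3.50, each at 1 probe set. For Actb the 3 control probe sets went the other way, with means of 14.83, 14.64 and 14.57 in air females and 14.57, 13.40 and 13.76 in air males. Vcl, Sod3, Sgpl1, Abca1, Msn, Mapk14, Azin1, Gusb and Tmcc3 were lower, with log2 differences from -4.16 to -3.54. These too were each measured at 1 probe set, which was not the brightest of its gene, and need not hold for the gene as a whole. After SHS the Y-linked genes were at 6.66, 5.34 and 5.31 and Xist at -7.79. Pik3cd (3.49), Pla2g15 (-3.74), Msrb3 (-3.51) and Sox4 (-3.51) joined the 20 largest, each at 1 probe set. The X-inactivation list was lower in SHS males, with 4 of 5 members lower (4 adjusted over the list alone, camera adjusted p = 0.00706, and adjusted p = 0.432 with an estimated correlation). T cell markers were lower as well, in 6 of 11 members (8 adjusted over the list alone, camera adjusted p = 0.0141, 0.0684 without SHS female replicate 3, and adjusted p = 0.988 with an estimated correlation). No list was called after air by camera, where 1 list had an unadjusted p under 0.05 with an estimated correlation and fry called 8. After air 22164 probe sets differed between the sexes, 49.2% of those tested, and after SHS 20066.

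The control probe sets of the arrays also differed by sex. Those for bacterial poly-A RNAs, which are added to the RNA before labelling and match no mouse gene, averaged 4.08 in air and in SHS females and 9.06 and 8.98 in air and SHS males. Each of the 24 separated all 8 male arrays from all 8 female arrays. The 18S ribosomal RNA probe sets averaged 6.86 and 6.74 in females and 13.7 and 13.9 in males. The 5′ minus 3′ difference of the Actb and Gapdh controls was 0.12 and 0.12 in females and -0.75 and -0.66 in males. Of 4380 genes with at least 2 called probe sets after air, 52.2% had called probe sets in opposite directions (95% exact interval 50.7 to 53.7). The level of the added RNAs and the sex of the mouse went together on all 16 arrays, so differences of mouse genes between the sexes could not be separated from differences in labelling. Between air and SHS within a sex none of the control classes differed in two-sided exact permutation tests (n = 4 and 4, p = 0.971 and 0.514 for poly-A controls of females and males, 0.4 and 0.514 for 18S, and 0.257 and 0.314 for hybridization controls).

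**Figure D4:**
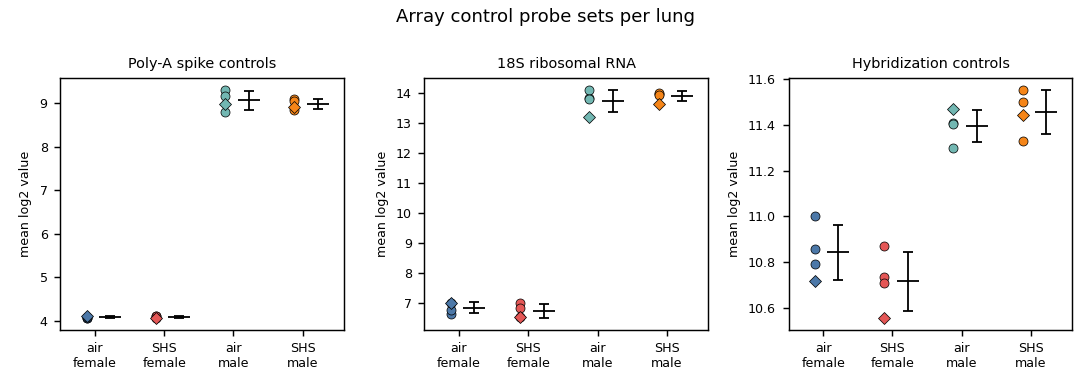
Mean log2 value of 3 classes of array control probe sets in each lung (vertical axes) for the 4 groups of 4 lungs, with diamonds for replicate 4 and bars for the group mean and SD. The poly-A controls average 4.08 in both female groups and 9.06 and 8.98 in air and SHS males.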

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

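The tests of the added control RNAs and of biology as the whole cause of the sex difference were chosen after the results they measure were seen. So were those of the excess of SHS female replicate 4, of eosinophil markers and of the splits for a single list. The tests of RNA integrity and of labelling by opposite directions within a gene were chosen before. So were those of the position of SHS male replicate 4 and of the counts over splits here.

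Among 688 groups of 4 values, 48 had an array far from the other 3, where chance gives about 1 in 20 groups, here 34.4. Values of single genes were taken at the brightest probe set of each gene. For Alad, Aspn, Mapk14, Gusb and Xist this is another probe set than the one named by the rule above. Of the 48, 12 were on SHS female replicate 4 and 11 on SHS male replicate 4. On SHS female replicate 4 the eosinophil granule genes Epx and Prg2 were at 5.05 and 6.52 (other SHS females 7.09 to 7.50 and 8.48 to 8.64), Rrm2 at 9.40, Mki67 at 9.49, Il4 at 6.17, Il33 at 11.66 and Aspn at 8.66, all lower than the other 3, and Mapk14 at 11.05, higher. The list medians of this array were -0.03 for complement, 0.05 for apoptosis and p53 targets and 0.08 for alveolar macrophages, lower than the other 3, and -0.01 for imprinted genes, higher. On SHS male replicate 4 Rrm2 at 9.63, Mki67 at 10.00, Top2a at 9.34, Pdia4 at 11.05 and Gusb at 10.58 were lower than in the other 3, and Fmo2 at 12.02, Scgb1a1 at 15.22 and Cckar at 9.75 higher. Its list medians were -0.50 for eosinophils, and 0.28 and 0.37 for endothelium and adipocytes.

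On other SHS arrays, Ifi27l2a was at 11.42 in female replicate 2, Xist at 12.92 in female replicate 1, Ifng and Muc5ac at 4.98 and 9.34 in male replicate 2, and Alad, Gpx2 and the type I interferon and neutrophil lists at 10.62, 10.00, 0.45 and 0.25 in male replicate 3. Among air females, Alad, Fmo2 and the X-inactivation list were at 9.77, 13.17 and 0.13 in replicate 1, Rrm2 at 8.28 in replicate 2, Cxcl5, Scgb1a1 and the NRF2 and endothelium lists at 5.54, 14.91, -0.06 and -0.11 in replicate 3, and Socs1 and the B cell list at 7.38 and -0.28 in replicate 4. Among air males, Ccng1 and Sqle were at 11.77 and 9.91 in replicate 2, Ddx4, Ces2b, Elovl6 and the eosinophil list at 4.00, 7.52, 7.23 and -0.25 in replicate 3, and Dnmt1 at 9.26 in replicate 4.

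The SHS effect differed between the sexes by camera in 14 lists, with adjusted p of 0.00197 for cardiac muscle, 0.00235 for goblet cells, 0.00488 for type I interferon and for apoptosis and p53 targets, 0.0179 for Th1 genes, endothelium and B cells, 0.0193 for natural killer cells, 0.0325 for IL-13 targets, ciliated cells and plasma cells, 0.0377 for T cells, and 0.0425 for club cells and adipocytes. All goblet cell markers except Gp2 were also on the list of IL-13 targets, so these calls overlap. With an estimated correlation the smallest adjusted p was 0.756 and fry called 0. Of 100 splits of the arrays 23 called as many lists, up to 25, so chance could not be excluded for this count. The level of the added control RNAs also went with sex on every array. These list differences could therefore not be separated from a difference in labelling either.

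Nearly 1 in 2 probe sets differed between the sexes, 22164 after air and 20066 after SHS, and among all 35 splits of the arrays the real one alone reached these counts (highest other 0 and 3). The bacterial poly-A controls, which no mouse makes, differed between the sexes by a median absolute log2 difference of 4.73, and all 24 separated the sexes, which says how the arrays were processed and nothing of mouse genes. A candidate explanation is that the arrays of the 2 sexes were labelled as separate batches, with added RNAs in only 1 of them. For mouse genes, 52.2% of those with several called probe sets after air had calls in opposite directions (interval 50.7 to 53.7), against at most 3.54% at the upper limit for the SHS effects, which goes with a labelling effect on each probe set and argues against biology as the whole cause. Which part of the difference at a given mouse gene was biological cannot be told apart from the batch, since both went with sex on every array.

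The lists of cell cycle, acute inflammation and IL-13 targets were called higher after SHS in both sexes by camera at its preset correlation, but not with an estimated one (adjusted p = 0.113, 0.113 and 0.313 in females and 0.168, 0.116 and 0.186 in males), and for IL-13 targets in females 3 of 35 splits were as extreme. A labelling batch between air and SHS arrays of a sex, of the kind seen between the sexes, is argued against by the share of genes with called probe sets in opposite directions, 1.40% in males (4 of 286, interval 0.382 to 3.54) and 0 of 193 in females, against 52.2% between the sexes. A milder batch need not turn probe sets of a gene in opposite directions, so this share cannot exclude it. In females the 5′ minus 3′ difference averaged 0.12 after air and after SHS, which argues against RNA integrity as the whole cause there. With this difference as a covariate each of the 3 lists kept at least 85.7% of its median in each sex. The count of probe sets fell from 2332 to 1178 in males and rose from 1294 to 1499 in females. In males the covariate cannot decide, since its spread within groups came mostly from SHS male replicate 4 (-0.88, other SHS males -0.60 to -0.58). That array also lay nearer air on the cell cycle list, so integrity and a weaker response could not be separated. The count of called lists did not exclude chance within a sex. As many were called by 5 of 35 splits in females (24, highest other 31) and 5 of 35 in males (14, highest other 23). For the averaged effect 4 of 100 splits called as many (20 lists, highest other 26). These 100 were only a draw of the possible splits, and a share of 4 among them is too imprecise to exclude chance. An effect of SHS in utero stays open as a hypothesis. Differences between litters, which could not be tested, and RNA integrity in males stay open beside it.

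The SHS arrays numbered 4 lay nearer the air arrays than the other SHS arrays of their sex at the probe sets called for SHS. A mislabelled air lung is argued against for the male array by its position on the air-to-SHS axis, 0.71, where the highest air male was at 0.28. For the female array the same test, fixed in advance, gave 0.21, inside the range of the air females (up to 0.23), as a mislabelled air lung would. A later test, chosen after that, tried in 2 versions that came out alike, gave it an excess of 0.19 over the air females (range -0.05 to 0.05) at the probe sets called higher in SHS males, which argues against a mislabelled air lung. Whether fewer eosinophils play a part stays open, since their low marker medians (a gap of -0.63 to the lowest of the other 3 in males, the smaller of the 2 sexes) prompted the question, and at -0.85 and -0.50 they lay below every air lung of their sex (lowest -0.06 and -0.25) and not nearer to air. RNA integrity stays open for the male array, whose 5′ minus 3′ difference was -0.88 against -0.60 to -0.58 in the other SHS males, as does a shared origin of the 2 arrays, whose deviations from their group means correlated at 0.480, the highest of 24 pairs with the same number. That correlation cannot decide on a shared origin. Both arrays deviated toward air and the SHS effects of the 2 sexes were alike, which would make their deviations correlate in any case.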

How the results depend on the processing

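Leaving out both SHS arrays numbered 4 was chosen after seeing the data, and the other alternatives before. No named gene and no list that was called in the main fit or in an alternative reversed its direction between the 2. Changes of sign in genes and lists called in neither were not counted. With a 1.5-fold minimum, however, the sex difference after SHS went from mostly higher in males (11006 against 9060) to mostly lower (3326 against 3762). The counts of probe sets stayed within 1.5 times under quantile normalization, centring, removal of dim probe sets, the replicate block and the trended robust prior, and the interaction had 0 probe sets called by limma in every one. The replicate block gave 1537 and 2439 in females and males.

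The female, male and averaged counts were 3985, 4398 and 7717 with array weights and 366, 463 and 406 with a 1.5-fold minimum, which left 8414 and 7088 for the sexes after air and after SHS. An adjusted p under 0.10 gave 2334 in females and 4073 in males, and the 8 female arrays alone gave 448. Both SHS arrays numbered 4 left out gave 3954 in females and 7520 averaged. The 1.5-fold minimum and the looser threshold change the counts by construction, and for the others the cause was not tested. With each array left out in turn, the counts ranged from 657 to 3604 in females, 1073 to 3153 in males, 3514 to 6983 averaged, 20225 to 22787 after air and 18319 to 20314 after SHS, and r between the sexes from 0.553 to 0.665.

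Gene lists depended most on the correlation between genes. With an estimated correlation 0 lists were called in females, males, the averaged effect, the interaction and the sexes after SHS, where 6, 8, 9, 1 and 1 had an unadjusted p under 0.05 and fry called 17, 11, 20, 0 and 6. For the sexes after air fry called 8 and the mean over all probe sets of a gene 2. Without dim probe sets 12 lists were called in the averaged effect and 1 for the sexes after SHS. In the interaction array weights gave 5 and the mean over probe sets 8. The cause was not tested. With each array left out, lists numbered 20 to 29 in females, 13 to 17 in males, 18 to 29 averaged, 4 to 17 in the interaction, 0 after air and 1 to 4 after SHS. Quantile normalization ended the female calls of extracellular matrix and ribosomal proteins.

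Of the values of named genes with 1 array left out, 6913 kept their side of the threshold, 724 lost a call and 27 gained one. A pseudocount did not apply to log2 values and was not run. Signal over background could not be set from the values, and the Trp control probe sets, whose RNA is not among those added, had group means of 3.52 to 3.61.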

Other observations

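The test of germline genes and the splits were set before their results were seen, except the splits for gene lists between the sexes and those list by list, and the genes Ddx4 and Afp, and the values of Epx and Prg2 above, were singled out after their values were seen.

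Some lists had members called in both directions. In the averaged effect Sqle, an enzyme of cholesterol synthesis, rose by 0.42 ± 0.08 and Elovl6, which lengthens fatty acids, by 0.39 ± 0.08, while the cholesterol exporters Abca1 and Abcg1 fell by 0.32 and 0.26, and the lipid and surfactant list was not called (camera adjusted p = 0.695). Uhrf1, which guides maintenance of DNA methylation and is also made by dividing cells, rose by 0.96 ± 0.08 (adjusted p = 2.58e-06) and its partner Dnmt1 by 0.29, with the list of DNA methylation and chromatin writers at a median of -0.03 (adjusted p = 0.948). Of 21 imprinted genes Mest rose by 0.38 and Plagl1 and Nnat fell by 0.41 and 0.51 (list adjusted p = 0.0729). Among monocyte and macrophage markers Cd14, a receptor for bacterial lipopolysaccharide, rose by 0.73 and Apoe fell by 0.58 (list adjusted p = 0.102), and Lyz2, a lysozyme of macrophages and alveolar type 2 cells, fell by 0.37 (adjusted p = 0.00011). Of the epithelial alarmins that start type 2 responses, Il33 rose by 0.70 (adjusted p = 0.000123) and Tslp fell by 0.54 (adjusted p = 0.00202).

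Afp, the fetal serum protein alpha-fetoprotein, rose by 1.06 in females and 1.15 in males (adjusted p = 0.000227 and 8.68e-05), and was higher in all 8 SHS lungs than in every air lung of the same sex. Ddx4, an RNA helicase of germ cells, stood at 3.21 to 4.00 in all 8 air lungs, at 6.29, 8.14 and 7.82 in SHS females and 7.71, 7.71 and 7.09 in SHS males, at 4.40 in the SHS male numbered 4 and within the air range in the SHS female numbered 4. It rose by 3.05 ± 0.77 in females and 2.98 ± 0.77 in males (adjusted p = 0.0381 and 0.0311), which are lower bounds, since control probe sets without their RNA were at 3.52 to 3.61. That germline genes rose together in SHS lungs was a hypothesis, and the median difference of the 13 other germline genes measured was 0.04, with Piwil2 at 0.50 and Sycp3 at -0.32 called, which argues against it. What raised Ddx4 alone was not tested.

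Chance was also examined by regrouping the arrays. For probe sets called after SHS, the real split alone reached its count among 35 in females (1294, highest other 1109) and in males (2332, highest other 1) and among 100 for the averaged effect (4652, highest other 11). This argues against chance for these counts if single mice are independent units. Differences between litters, which were not given, are not excluded by it, and within a sex 1 in 35 is the smallest share possible. For the interaction all 100 splits reached the 0 called by limma, as any split must, so this count tests nothing (highest other 1), and 3709 probe sets had an unadjusted p under 0.05. The correlation of the SHS effects of the sexes, 0.624, was reached by 1 of 100 splits, the real one (highest other 0.457). That argues against chance, again only if single mice are independent units. Litters common to females and males, which the splits could not keep together, are not excluded. In females the split that exchanged SHS female replicate 4 with air female replicate 1, at 0.21 and 0.23 on the air-to-SHS axis, called 1109 probe sets against 1294 for the real one. List by list, the real split alone was as extreme for 5 of the 24 lists called in females (cell cycle, acute inflammation, oxidative phosphorylation, hypoxia and glycolysis, complement). The same held for 7 of the 14 in males (the same 5, IL-13 targets and NRF2 targets). A share of 1 in 35 is the smallest possible, and it was not adjusted over the 51 lists tested. Chance was thus not excluded for any single list. For the other 19 lists in females 2 to 22 of 35 splits were as extreme, with 3 for IL-13 targets, 7 for dendritic cells, 9 for B cells, 11 for neutrophils, 12 for lung development, 17 for extracellular matrix, 18 for endothelium and 22 for fibroblasts. For the other 7 in males 2 to 16 were, with 5 for goblet cells, 6 for xenobiotic metabolism, 7 for heat shock, 9 for cardiac muscle and 16 for type I interferon. The share of splits as extreme was under 0.05 for 9 of 20 lists in the averaged effect and for 1 of 14 in the interaction. It was again not adjusted over the lists and does not exclude chance for a single list. Up to 50 and 48 of 100 splits were as extreme for the others. The 1 in the interaction, apoptosis and p53 targets (3 of 100 splits), was called neither with an estimated correlation (adjusted p = 0.756) nor by fry (0.504). For lists between the sexes after air, all 35 of 35 splits reached the 0 called, as any split must, so this count tests nothing (highest other 12). After SHS 33 of 35 splits called as many as the 2 (highest other 24), so chance was not excluded for the count, while list by list the real split alone was as extreme for X-inactivation genes and 8 of 35 were for T cells.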
